A study of Mus musculus with 12 samples.

How the data were processed

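RNA was measured in 12 libraries of mouse hearts, 3 in each of 4 groups made of genotype and age. Hearts were frozen after genotyping and RNA was extracted with TRIzol, per the labels' protocols. The design text names the BGISEQ-500 platform for the libraries, and the labels' protocols name an Illumina procedure for them. The submitters' processing notes list HISAT2 version 2.0.4, STAR version 2.3.0, DESeq2 and the genome builds mm8 and mm9, without the role or order of any of them. The build and the counting tool are therefore not known, and no coordinates are given here. The deposited values are expected counts per gene and library, for which no normalization is recorded, per the file headers. The headers call them read counts, and 29.3% to 32.8% of the genes in a library hold decimals. The strand setting and the handling of reads that match several genes are not recorded, so values of near-identical or overlapping genes (Hspa1a beside Hspa1b, or Myh6 beside Myh7, which are alike in long stretches) are uncertain. A cDNA of Dyrk1b and the animal's own Dyrk1b are counted as 1 gene.

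The files pair a gene ID with a symbol for 18444 genes, and 18313 of the IDs (99.3%) were found in a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Mitochondrially encoded transcripts are not among the genes listed. The table that joins the 12 libraries was not used, since it holds the values of the 12 single files. Library totals run from 11174527 to 17095351 counts. Replicates of a group differ by more than counting error (chi-square per degree of freedom of 4.47 to 28.06 between pairs), so they were not taken as repeated sequencing of 1 library. Pools of hearts could give such values too, so that each library is 1 heart is an assumption made throughout.

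Expected counts were rounded to whole numbers, a step chosen when the decimals were seen. Genes were filtered with filterByExpr on the 4 groups, which left 14212, and libraries were scaled with TMM in edgeR 4.0.16 under R 4.3.3. All 12 libraries were fitted in 1 quasi-likelihood model with a mean per group and 8 residual degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Contrasts were DYRK1B-Tg against WT at P3 and at P56, the difference of these effects (interaction), and P56 against P3 in WT. Standard errors (SE) of log2 fold changes are the absolute change divided by the square root of the F statistic. CPM are the values of the cpm function of edgeR with TMM-scaled library totals, given as means with the standard deviation over 3 hearts.

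A set of 42 gene lists (pathways, muscle isoforms, cell type markers and quality lists) was fixed, and 36 lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. For each list the calls were also counted with p-values adjusted over the list alone. The comparisons, tests, lists, rule for named genes and alternatives were fixed before the data were examined, apart from those named here as added. Named genes are Dyrk1b, the 8 highest and 8 lowest fold changes among called genes per genotype comparison (5 and 5 for the interaction and for age) with a mean of at least 1 CPM and, outside the interaction, groups that do not overlap, up to 3 members with the lowest p of each list, and Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Ppargc1a, Stat3, Col1a1, Col3a1 and Cpt1b. Not every gene the rule gives is named, and some results for single genes are not reported here. Genes named outside the rule, chosen after their values were seen, are Thbs2, Nebl, Herpud1, Mcl1, Gm14296, Serpina3n, Lcn2, Fos, Kcne1 and Hcn4.

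Alternatives were RLE size factors, no filter on low counts, leaving out the 10 genes with most counts, the replicate number as a block, each replicate left out in turn, a fit of the compared groups alone, a minimum absolute log2 fold change of 1, DESeq2 1.42.0 in place of edgeR, and, for lists, a correlation estimated per list and the rotation test fry. A sex term (Y-linked counts of at least 10 CPM) and thinning to the smallest total of 11174527 counts were added after the data were seen. Splits of the libraries were counted, the real one included: all 10 of 3 against 3, and 100 for the interaction, of which all but the real one were drawn at random. The fit and the list test were tested on simulated data with 200 changed genes. For DYRK1B-Tg against WT at P3 (14102 genes simulated) the fit recovered 41% of 1.5-fold and 81.8% of 2-fold changes, with 10.1% false calls. For DYRK1B-Tg against WT at P56 (14059 genes simulated) it recovered 54.5% and 80.8%, with 3.4% false calls. In both simulations the list with a planted change was called and 0 of the 35 other lists were called by camera. The simulated genes varied independently of each other, whereas the correlation estimated for the real complex I list at P56 was 0.764. The simulations therefore cannot show how often camera calls a list of correlated genes without a change.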

Results

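Transcript levels were measured by RNA sequencing in mouse hearts that carry a transgene for the protein kinase DYRK1B (DYRK1B-Tg) and in hearts of wild-type (WT) littermates, all C57BL/6. In the transgene, a Dyrk1b cDNA is driven by the promoter of alpha myosin heavy chain, a contractile protein of heart muscle cells. The 12 libraries form 4 groups of 3 hearts, namely WT and DYRK1B-Tg at postnatal day 3 (P3) and at 8 weeks (P56). Library totals were 15742474 to 16756522 counts in WT at P3 and 16854195 to 17095351 in the libraries labelled DYRK1B-Tg at P3. At P56 they were 11174527 to 12099794 in WT and 12760002 to 13231968 in DYRK1B-Tg. The leading principal component held 78.1% of the variance and parted the ages. The next held 8.6% and parted the genotypes at P56, where WT hearts lay between -35.3 and -33.7 and DYRK1B-Tg hearts between 23.9 and 45.6.

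Dyrk1b itself (gene ID 13549) was read first, since it checks the genotype labels. At P56 it rose from 96.9 ± 7.43 CPM in WT to 798 ± 178 CPM in DYRK1B-Tg (mean ± SD, n = 3), an 8.24-fold difference (log2 fold change 3.04, SE 0.15, edgeR adjusted p = 2.37e-07). At P3 it stood at 75.3 ± 3.35 CPM in WT and at 84.7 ± 7.84 CPM in the libraries labelled DYRK1B-Tg, a log2 fold change of 0.17 (SE 0.14, adjusted p = 0.927). The 95% interval of that change ran from -0.13 to 0.47, so it allowed at most a 1.38-fold increase. The Dyrk1b level thus does not bear out the DYRK1B-Tg label at P3. It cannot refute that label either, since a transgene not yet transcribed would give the same level. A direction given below for P3 is one between labels.

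**Figure D1:**
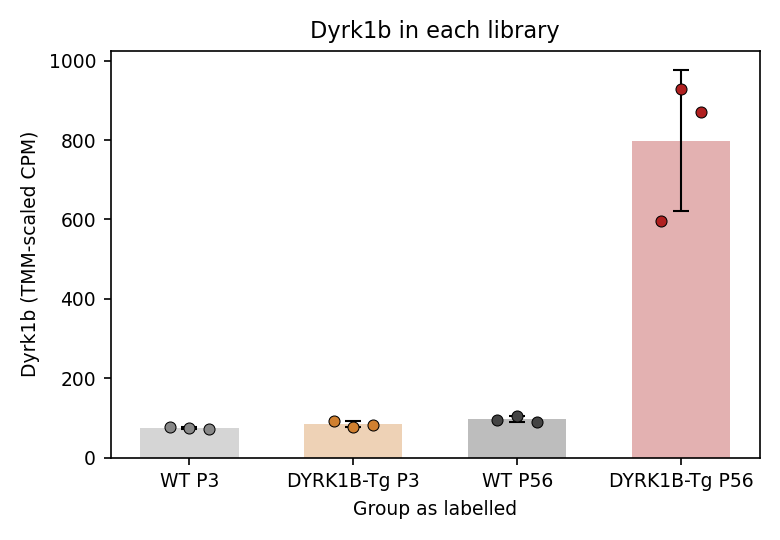
Dyrk1b in TMM-scaled CPM (vertical axis, from 0) in the 4 groups as labelled, with a point per library, bars for the mean and error bars for the standard deviation (n = 3). The DYRK1B-Tg hearts at P56 lie between 596 and 928.6 CPM, and every other library, the libraries labelled DYRK1B-Tg at P3 included, lies at or below 105.1 CPM.

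The comparison at P56 asks what the transgene goes along with in the adult heart. Transcripts of cardiac stress and of the extracellular matrix rose, and many transcripts of mitochondrial energy metabolism fell by smaller amounts. Acta1 (gene ID 11459), the skeletal muscle alpha-actin, rose from 368 ± 152 to 6544 ± 939 CPM (log2 fold change 4.15, SE 0.38, adjusted p = 1.26e-05). Nppb, which encodes a natriuretic peptide released by strained heart muscle, rose from 82.3 ± 17.1 to 736 ± 171 CPM (3.16, SE 0.36, adjusted p = 6.66e-05), and Nppa, its atrial relative, rose by 2.17 (SE 0.40, adjusted p = 0.00176). Myh7, the slow myosin heavy chain, rose by 3.87 (SE 0.54, adjusted p = 2.99e-04) with a wide spread: DYRK1B-Tg replicate 1 held 4997 CPM and the other hearts 892 and 1178 CPM. In the list of cardiac stress and hypertrophy markers, 15 of 16 tested genes rose, also 15 when adjusted over the list alone, with a median log2 fold change of 2.17. They include Rcan1, an inhibitor of the phosphatase calcineurin (2.60, SE 0.14), and Cilp, a secreted matrix protein (4.23, SE 0.23). The list was called by camera (adjusted p = 3.88e-30) and stayed called with an estimated correlation (adjusted p = 0.0152). Beside it, 6 of 15 immediate early genes, a list for signs of tissue handling, rose and 1 fell, with a median of 0.78, which was 0.32 without DYRK1B-Tg replicate 1. Atrial markers, Nppa among them, had 2 of 9 genes higher and were not called as a list (median 1.30, adjusted p = 0.324). Their median was 0.00 without DYRK1B-Tg replicate 3, 0.74 without WT replicate 1 and 2.17 without WT replicate 3.

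Across all 14212 genes tested, edgeR called 2008 higher and 1640 lower in DYRK1B-Tg at P56, which is 25.7%, and 593 and 210 of them changed at least 2-fold. DESeq2 called 1952 higher and 1735 lower. Among the largest increases were Edn3, a peptide of the endothelin family (5.42, SE 0.29, adjusted p = 2.65e-07), Nos1, the neuronal nitric oxide synthase (4.98, SE 0.35, adjusted p = 1.86e-06), and Sypl2, a membrane protein of the muscle triad (0.93 ± 0.31 to 29.9 ± 10.4 CPM, adjusted p = 1.87e-06). Among the largest decreases were Lad1, an anchoring filament protein (-3.26, SE 0.44, adjusted p = 2.42e-04), Shisa6, a partner of glutamate receptors (-3.95, SE 0.60, adjusted p = 4.99e-04), and Ky, a muscle protein needed for normal growth of muscle (-2.84, SE 0.49, adjusted p = 0.00119). Without DYRK1B-Tg replicate 1, which lay apart from replicates 2 and 3 (45.6 against 23.9 and 31.9 on the component that parts the genotypes), edgeR called 1642 higher and 1365 lower.

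**Figure D2:**
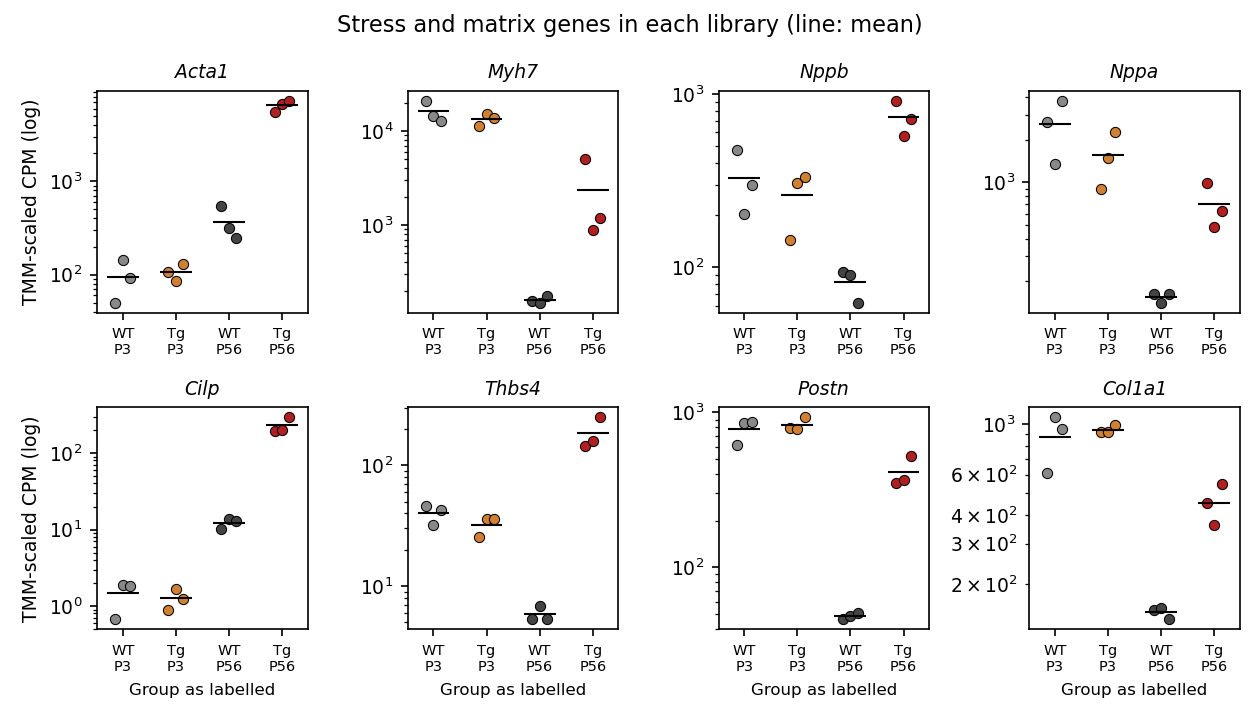
Levels of 8 genes in TMM-scaled CPM (vertical axes, log scale) in the 4 groups as labelled, with a point per library and a line for the group mean (n = 3). Acta1 lies at 368 CPM in WT and 6544 CPM in DYRK1B-Tg at P56 on average, and Myh7, Nppb, Nppa, Cilp, Thbs4, Postn and Col1a1 are likewise higher in DYRK1B-Tg than in WT at P56.

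Matrix genes formed the broadest increase. Of 36 tested matrix genes 34 rose, the same number when adjusted over the list alone, with a median of 1.25 (camera adjusted p = 2.58e-39, adjusted p = 0.0444 with an estimated correlation). Thbs4, a thrombospondin of the matrix, rose from 5.82 ± 0.89 to 184 ± 57.3 CPM (4.98, SE 0.26, adjusted p = 2.65e-07). Postn, made by activated fibroblasts, rose by 3.09 (SE 0.17, adjusted p = 3.31e-07), Col1a1 by 1.59 (SE 0.18, adjusted p = 7.02e-05) and Col3a1 by 0.80 (SE 0.18, adjusted p = 0.00651). The 1 matrix gene that fell was Thbs2, another thrombospondin (-1.06, SE 0.15, adjusted p = 2.87e-04), named after its value was seen. Beside the matrix genes, 9 of 12 fibroblast markers rose, with a median of 0.91, and 10 of the 12 are not on the matrix list. Mfap5, a microfibril protein, was among them (1.81, SE 0.19, adjusted p = 3.25e-05). The fibroblast list was called by camera (adjusted p = 2.32e-08) but not with an estimated correlation (adjusted p = 0.0974). Epicardial and mesothelial markers had a median of 1.77, with 3 of 9 higher, and were not called as a list (adjusted p = 0.0656). That median was -0.07 without DYRK1B-Tg replicate 1, and the list was called without WT replicate 1 (adjusted p = 0.0146), DYRK1B-Tg replicate 2 (0.00443) or replicate 3 (0.00494). Endothelial markers went the other way: 7 of 12 fell, 8 when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.00254, adjusted p = 0.0791 with an estimated correlation). Tek, an angiopoietin receptor, was among them (-0.41, SE 0.08, adjusted p = 0.00173). The correlation estimated for the endothelial list was 0.002, below the preset 0.01, so correlated genes of this list do not account for its higher adjusted p. Of 10 smooth muscle and pericyte markers 6 fell and 2 rose, the decreases including Rgs5 (-0.66, SE 0.12, adjusted p = 0.00172). That list was not called (adjusted p = 0.126), but it was called without WT replicate 3 (adjusted p = 0.0308) and without DYRK1B-Tg replicate 2 (adjusted p = 0.0496). Macrophage markers were not called as a list (median 0.23, adjusted p = 0.52), and their median was 0.11 without DYRK1B-Tg replicate 1 and 0.12 without WT replicate 3.

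Transcripts for the use of fuels in mitochondria fell together at P56. In the list of the TCA cycle and pyruvate dehydrogenase, 18 of 20 genes fell, 18 also when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 4.11e-10, adjusted p = 0.284 with an estimated correlation). Suclg2, a subunit of succinyl-CoA ligase, fell from 233 ± 2.26 to 149 ± 8.93 CPM (-0.65, SE 0.06, adjusted p = 1.48e-05). In the list of branched-chain amino acid and ketone catabolism 14 of 17 fell, with a median of -0.40 (camera adjusted p = 4.27e-09, adjusted p = 0.0791 with an estimated correlation). When adjusted over the list alone 16 fell and 1 rose. Bckdha, a subunit of the branched-chain keto acid dehydrogenase, stood at -0.78 (SE 0.09, adjusted p = 6.15e-05). In the list of fatty acid uptake and oxidation 17 of 29 fell, 18 when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 2.06e-08, adjusted p = 0.284 with an estimated correlation). Hadhb, a subunit of the trifunctional protein of beta-oxidation, changed by -0.65 (SE 0.08, adjusted p = 1.6e-04), whereas Cpt1b, the muscle carnitine palmitoyltransferase, did not pass the test (-0.10, SE 0.06, adjusted p = 0.27).

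Some nuclear genes of the respiratory chain fell as well, while most of those of complexes I and IV were not called. Of complex I subunits 11 of 36 fell, 17 when adjusted over the list alone, with a median of -0.25 (camera adjusted p = 2.28e-05, adjusted p = 0.621 with an estimated correlation), such as Ndufs1 (-0.61, SE 0.07, adjusted p = 6.12e-05). Of complexes II and III 9 of 14 fell, with a median of -0.32 (camera adjusted p = 1.4e-05, adjusted p = 0.418 with an estimated correlation), such as Sdha (-0.62, SE 0.07, adjusted p = 5.01e-05). Of ATP synthase 9 of 17 fell, 11 when adjusted over the list alone, with a median of -0.30 (camera adjusted p = 1.4e-05, adjusted p = 0.418 with an estimated correlation), such as Atp5a1 (-0.56, SE 0.08, adjusted p = 2.25e-04). Of complex IV 5 of 13 fell, with a median of -0.19 (camera adjusted p = 0.0108, adjusted p = 0.621 with an estimated correlation), and without WT replicate 1 that list had 3 and was not called (adjusted p = 0.0528). Of the regulators of mitochondrial biogenesis 8 of 22 fell, 9 when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.00177, adjusted p = 0.284 with an estimated correlation). Ppargc1a, the coactivator PGC-1 alpha, was among them (-0.67, SE 0.16, adjusted p = 0.00973).

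**Figure D3:**
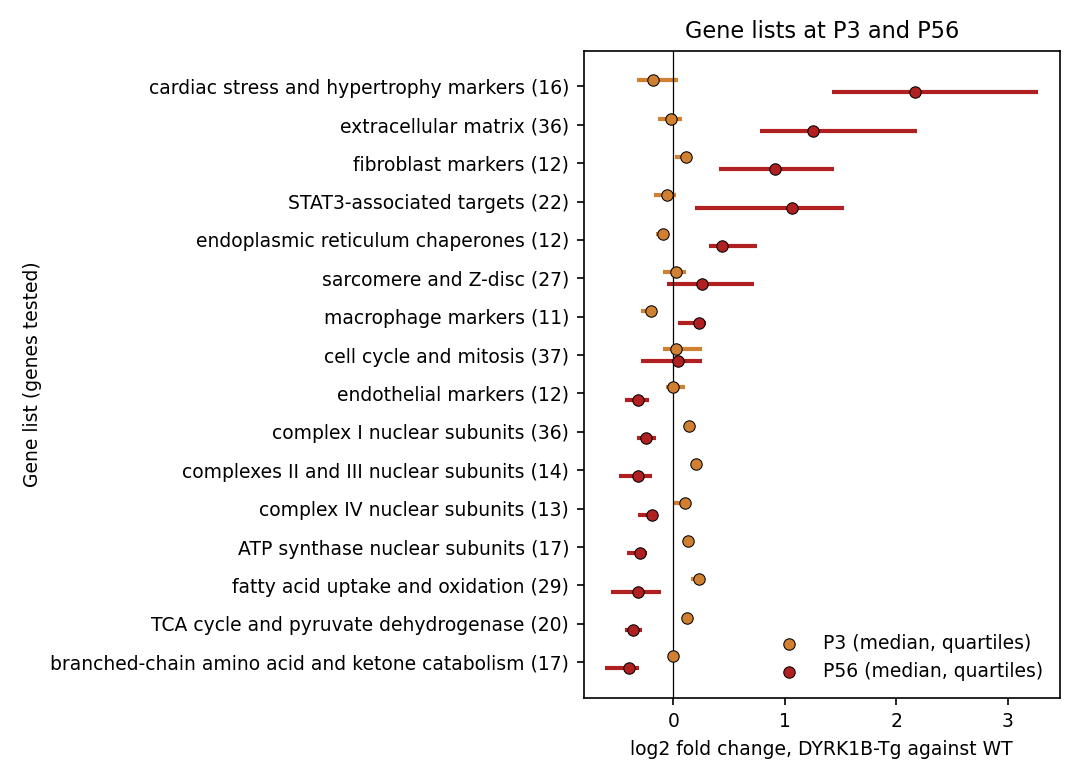
Median log2 fold change of DYRK1B-Tg against WT (horizontal axis) for 16 gene lists, with the tested genes in brackets, at P3 (orange) and at P56 (red). Points are medians over the genes of a list and lines their quartiles; at P56 the medians run from -0.40 for branched-chain amino acid and ketone catabolism to 2.17 for cardiac stress and hypertrophy markers, and the P3 values compare libraries by label.

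Within the contractile apparatus, 14 of 27 sarcomere and Z-disc genes rose and 2 fell at P56, and 15 and 2 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 1e-04, adjusted p = 0.284 with an estimated correlation). Csrp3, a Z-disc protein of stretch sensing, rose by 1.06 (SE 0.11, adjusted p = 2.61e-05) and Flnc, filamin C, by 1.37 (SE 0.10, adjusted p = 2.48e-06). The decreases were Tnni3, cardiac troponin I (-0.55, SE 0.10, adjusted p = 0.00189), and Nebl, nebulette (-0.23, SE 0.07, adjusted p = 0.0338). Atp2a2, the calcium pump of the sarcoplasmic reticulum, changed by -0.46 (SE 0.09, adjusted p = 0.00207). Myh6, the gene of alpha myosin heavy chain, stood at 39576 ± 1507 CPM in WT and 31205 ± 2935 CPM in DYRK1B-Tg (-0.34, SE 0.15, adjusted p = 0.112), and passed only in the fit of the 2 groups alone (adjusted p = 0.0198). Of 12 chaperones of the endoplasmic reticulum 8 rose, 10 when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 9.9e-04, adjusted p = 0.418 with an estimated correlation). Manf rose by 0.86 (SE 0.12, adjusted p = 3.51e-04), while Herpud1, a factor of protein degradation at that organelle, fell (-0.63, SE 0.17, adjusted p = 0.0169). Among 22 targets linked to the transcription factor STAT3, 8 rose and 1 fell, and 13 and 2 when adjusted over the list alone, with a median of 1.06 (camera adjusted p = 0.00233, adjusted p = 0.621 with an estimated correlation). Stat3 rose by 0.66 (SE 0.11, adjusted p = 9.61e-04), Timp1, an inhibitor of matrix proteases, by 2.94 (SE 0.32, adjusted p = 4.93e-05) and Fgl2, a fibrinogen-like protein, by 1.23 (SE 0.16, adjusted p = 1.88e-04). The 1 that fell was Mcl1, which restrains cell death (-0.26, SE 0.07, adjusted p = 0.0113). The number of genes called in this list and the size of its median depended on single hearts. Without DYRK1B-Tg replicate 1, 6 rose, 2 fell and the median was 0.33, while 14 rose without replicate 2 and 12 without replicate 3.

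The comparison at P3 asks the same of the newborn heart, by label. Libraries labelled DYRK1B-Tg hardly parted from WT: edgeR called 0 genes higher and 0 lower, with 681 at an unadjusted p under 0.05 where chance gives 711, and DESeq2 called 1, with 622 at an unadjusted p under 0.05. This was Gm14296, which was lower (-1.57, DESeq2 adjusted p = 4.26e-06). That gene, named after its value was seen, stood at -1.56 in edgeR (adjusted p = 0.157). The stress and matrix genes of the adult comparison had log2 fold changes of 0.19 for Acta1 (SE 0.34), -0.27 for Myh7 (SE 0.48), -0.32 for Nppb (SE 0.33), -0.75 for Nppa (SE 0.38) and 0.11 for Col1a1 (SE 0.18), with adjusted p from 0.927 to 0.955. Camera at the preset correlation called 9 lists higher and 3 lower, and 0 with an estimated correlation or with fry. Among the higher lists, fatty acid uptake and oxidation had a median of 0.23 (camera adjusted p = 2.13e-14, adjusted p = 0.373 with an estimated correlation), where 11 of 29 genes passed when adjusted over the list alone. Complexes II and III had 0.20 (4.6e-09, adjusted p = 0.712 with an estimated correlation), and complex I had 0.14 (3.62e-09, adjusted p = 0.774 with an estimated correlation). Complex IV, ATP synthase, the TCA cycle, glycolysis, adult-type muscle isoforms and interferon-stimulated genes had medians of 0.10 to 0.25, with adjusted p of 0.712 to 0.774 with an estimated correlation. The lower lists were macrophage markers at -0.20 (adjusted p = 0.373 with an estimated correlation), endoplasmic reticulum chaperones at -0.09 (adjusted p = 0.774) and atrial markers at -0.75 (adjusted p = 0.774). WT replicate 1 stood apart, with a chi-square per degree of freedom of 28.06 and 26.52 to the other WT hearts and 9.36 between these. Without it the higher lists numbered 4, and the medians were 0.05 for complex I, 0.07 for complexes II and III and for the TCA cycle, 0.00 for complex IV, 0.03 for ATP synthase and for glycolysis, 0.02 for adult-type isoforms and 0.09 for interferon-stimulated genes. Other hearts moved list medians too. That of interferon-stimulated genes was 0.61 without WT replicate 2, 0.16 without WT replicate 3, and 0.45 and 0.02 without the libraries labelled DYRK1B-Tg replicates 2 and 3. Glycolysis stood at 0.17 and adult-type isoforms at 0.20 without WT replicate 2, adult-type isoforms at 0.06 without the library labelled DYRK1B-Tg replicate 1, and complex IV at 0.16 and macrophage markers at -0.13 without WT replicate 3. Atrial markers stood at -0.38 without WT replicate 3, and at -0.46 and -1.20 without the libraries labelled DYRK1B-Tg replicates 1 and 3. The lower lists numbered 5 without the library labelled DYRK1B-Tg replicate 2 and likewise without replicate 3. Y-linked transcripts were at 3.1 CPM in WT replicate 2 and 2.8 CPM in the library labelled DYRK1B-Tg replicate 3, and between 126.3 and 194.1 CPM in the other P3 hearts. At P56 every heart lay between 132.7 and 166 CPM. The comparison at P56 thus holds only hearts with Y-linked transcripts, and comparisons between ages differ in part by sex.

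The interaction asks whether the effect of genotype differs between ages, again with the P3 labels as given. Dyrk1b had a difference of 2.87 (SE 0.20, adjusted p = 1.08e-05) between its effect at P56 and at P3. Thbs4 (5.28, SE 0.34), Postn (2.99, SE 0.23), Acta1 (3.97, SE 0.49) and Nppb (3.48, SE 0.48) had more positive effects at P56, with adjusted p of at most 7.07e-04, and Hadhb (-0.90, SE 0.12), Suclg2 (-0.74, SE 0.08) and Sdha (-0.73, SE 0.10) more negative ones, with adjusted p of at most 4.84e-04. The largest differences included Lrp8, a lipoprotein receptor (5.90, SE 0.73, adjusted p = 3.51e-04), Edn3 (5.73, SE 0.93, adjusted p = 0.00188), Lrp2bp (-3.32, SE 0.52, adjusted p = 0.00146) and Snai3, a transcription factor of the snail family (-3.61, SE 0.73, adjusted p = 0.00674). In all, edgeR called 1196 genes more positive and 913 more negative, and 2029 of these 2109 (96.2%) were also called at P56 with the same sign. Without the library labelled DYRK1B-Tg P3 replicate 1, the 913 became 589. With the replicate number as a block, 693 genes were called more positive and 368 more negative. Among the lists, cardiac stress markers differed by a median of 2.58 (camera adjusted p = 9.13e-28, adjusted p = 0.0183 with an estimated correlation) and matrix genes by 1.26 (5.18e-38, adjusted p = 0.0508 with an estimated correlation). Over all genes tested, 47.1% had the same sign of effect at both ages.

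The change from P3 to P56 in WT gives the scale of change with age and checks the age labels. Tnni1, the slow skeletal troponin I of the fetal heart, fell from 1338 ± 108 to 0.38 ± 0.11 CPM (-11.74, SE 0.24, adjusted p = 1.76e-11), and Igf2, a fetal growth factor, fell from 3465 ± 322 to 58.0 ± 4.89 CPM (-5.90, SE 0.17, adjusted p = 8.69e-11). Tcap, a Z-disc protein, rose by 5.05 (SE 0.15), Ckmt2, the mitochondrial creatine kinase, by 3.93 (SE 0.14), and Slc2a4, the insulin-dependent glucose transporter, by 3.34 (SE 0.10), with adjusted p of at most 3.28e-10. Of 37 cell cycle genes 35 fell, with a median of -2.84 (camera adjusted p = 5.12e-17, adjusted p = 0.0966 with an estimated correlation), such as Mki67 (-2.95, SE 0.12). Of 36 matrix genes 32 fell, with a median of -2.10 (camera adjusted p = 7.73e-14, adjusted p = 0.124 with an estimated correlation), such as Fn1 (-3.25, SE 0.13). Markers of other cell types fell beside them: epicardial and mesothelial markers in 9 of 9 genes (median -4.67, camera adjusted p = 0.00425), atrial markers in 8 of 9 (median -4.24, camera adjusted p = 0.0348) and erythroid markers in 8 of 9 (median -2.51, camera adjusted p = 0.0106). With an estimated correlation their adjusted p were 0.457, 0.577 and 0.37. The 36 complex I genes rose with a median of 1.28 (camera adjusted p = 5.12e-17, adjusted p = 0.23 with an estimated correlation). Branched-chain and ketone catabolism, with 17 of 17 genes higher, fetal-type isoforms, with 14 of 19 lower, macrophage markers, with 10 of 11 higher, and antioxidant enzymes, with 15 of 18 higher, stayed called with an estimated correlation (adjusted p = 0.0372 for each). edgeR called 4799 genes higher and 4994 lower, 68.9% of those tested.

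Both the P56 comparison and the age comparison rest on the WT hearts at P56. Of the genes called in both, 2720, the effect of genotype ran against the change with age in 1604 (59%). Postn and Col1a1, which fell with age by 4.01 and 2.54, were higher in DYRK1B-Tg at P56, and Ndufs1 and Sdha, which rose with age, were lower. Genes higher in DYRK1B-Tg and lower with age numbered 798, against 706 for independent lists, and genes lower in DYRK1B-Tg and higher with age numbered 806, against 554. Genes higher in both numbered 682, against 678, and genes lower in both 434, against 576. Over all genes the covariance of the effects was -0.23, and simulated groups without any effect, which share the same WT hearts, gave -0.06 on average over 20 simulations. The share of genes with opposite signs went the other way, at 53.8% over all genes tested against 67.5% (66.7 to 68.4) in these simulations.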

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

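The tests of library size by thinning, of heart muscle and fibroblast content, of exchanged labels, of changes as large as at P56 missed at P3, of an absent transgene and of a return to the neonatal state were chosen only after the results they bear on were seen. The counts of other splits, the test of power at P3 and the covariance with shared WT hearts were set earlier.

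The effect of genotype differed between ages by the interaction test of edgeR for 1196 genes that were more positive and 913 that were more negative at P56 than between the labels at P3. Dyrk1b at P3 stood near the WT level in the libraries labelled DYRK1B-Tg. Among stress and muscle genes the differences on the log2 scale were 2.87 for Dyrk1b, 3.97 for Acta1, 4.14 for Myh7, 2.92 for Nppa, 3.48 for Nppb, 2.61 for Rcan1, 4.45 for Cilp, 1.19 for Csrp3, 1.41 for Flnc, -0.67 for Tnni3 and -0.48 for Atp2a2. Among matrix and vessel genes they were 5.28 for Thbs4, 2.99 for Postn, 1.48 for Col1a1, -1.08 for Thbs2, 2.91 for Timp1, 1.80 for Mfap5, -0.38 for Tek and -0.76 for Rgs5. Among metabolic genes they were -0.90 for Hadhb, -0.74 for Suclg2, -0.78 for Bckdha, -0.73 for Sdha, -0.78 for Ndufs1, -0.70 for Atp5a1, 1.21 for Pfkp, 0.48 for Ldha, -0.55 for Ldhb, 1.60 for Pycr1 and -0.54 for Shmt2. Among the remaining genes they were 5.73 for Edn3, 5.09 for Nos1, 4.70 for Sypl2, -2.83 for Lad1, -3.01 for Ky, -2.69 for Shisa6, 0.73 for Stat3, 1.21 for Fgl2, 1.05 for Manf, -1.13 for Kcnip2, -1.07 for Kcnj2, -1.52 for Ccnd2, 3.01 for Cdkn2b, -1.10 for Cdkn1c, 0.82 for Cenpa, -1.34 for Cenpf, 2.53 for Atf3 and 3.80 for Hspa1a. Calls of the interaction that ended when 1 library was left out were those of Atp2a2 (adjusted p = 0.0548 without WT P3 replicate 3, 0.0577 without the library labelled DYRK1B-Tg P3 replicate 1 and 0.0527 without WT P56 replicate 2) and of Cdkn2b (0.067 without WT P3 replicate 2 and 0.053 without the library labelled DYRK1B-Tg P3 replicate 2). The call of Ldha ended without WT P3 replicate 2 (0.0511) or 3 (0.0519), the library labelled DYRK1B-Tg P3 replicate 3 (0.0602), WT P56 replicate 3 (0.0567) or DYRK1B-Tg P56 replicate 3 (0.0529). That of Tek ended without WT P3 replicate 2 (0.0604), the libraries labelled DYRK1B-Tg P3 replicate 2 (0.0505) or 3 (0.0696), WT P56 replicate 1 (0.0587) or 2 (0.0733), or DYRK1B-Tg P56 replicate 2 (0.0611). That of Shisa6 ended without WT P3 replicate 1 (0.0639) or 2 (0.0622), the libraries labelled DYRK1B-Tg P3 replicate 2 (0.104) or 3 (0.1), WT P56 replicate 1 (0.0522) or 2 (0.0869), or any of the DYRK1B-Tg P56 replicates (0.056, 0.0909 and 0.0973). Col3a1, Myh6, Cpt1b and Ppargc1a did not pass the interaction test, but without WT P3 replicate 1 Col3a1 (0.92, adjusted p = 0.0034) and Ppargc1a (-0.73, adjusted p = 0.0157) did.

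Among gene lists, camera called a difference between ages with medians of 2.58 for cardiac stress markers, 1.26 for matrix genes, 0.78 for fibroblast markers, 0.27 for sarcomere and Z-disc genes, 1.04 for STAT3-linked targets, 0.54 for endoplasmic reticulum chaperones, 1.99 for epicardial and mesothelial markers and 2.38 for atrial markers. The atrial member Bmp10 has a count of 0 in both groups at P56. The atrial call ended without WT P3 replicate 3 (median 1.71, adjusted p = 0.0946), the library labelled DYRK1B-Tg P3 replicate 1 (1.95, 0.0645), WT P56 replicate 1 (1.79, 0.0748) or DYRK1B-Tg P56 replicate 3 (0.78, 0.111). The epicardial call ended without WT P56 replicate 2 (1.46, 0.0581) or DYRK1B-Tg P56 replicate 1 (0.02, 0.336). The median of STAT3-linked targets was 0.39 without DYRK1B-Tg P56 replicate 1, and that of sarcomere and Z-disc genes 0.17 without WT P56 replicate 2. Camera called lower medians of -0.40 for complex I, -0.51 for complexes II and III, -0.36 for complex IV, -0.41 for ATP synthase, -0.53 for fatty acid uptake and oxidation, -0.53 for the TCA cycle and pyruvate dehydrogenase, -0.43 for branched-chain amino acid and ketone catabolism, -0.19 for regulators of mitochondrial biogenesis, -0.26 for adult-type muscle isoforms and -0.34 for endothelial markers. Without WT P3 replicate 1 the medians were -0.28 for complex I, -0.25 for complex IV and -0.33 for ATP synthase. Without WT P3 replicate 3 they were -0.49, -0.44 and -0.48. Adult-type isoforms stood at -0.21 without WT P3 replicate 1 (camera adjusted p = 0.0439). With an estimated correlation 1 of these 18 calls, that of the stress markers, was made, while fry called 16 lists.

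Other splits of the libraries were refitted in the same way, and each count of splits below includes the real split. For the interaction 3 of 100 splits, the real one among them, gave at least the real 2109 genes, the highest other giving 2263. The 13 splits that keep the real groups at P56 gave 1474 to 2263 genes, 3 of them at least the real count, and the other 87 at most 1. The share under 0.05 thus rests on the groups at P56, for which the splits are too few, and excludes nothing about the grouping at P3. For the lists of the interaction 16 of 100 splits reached the real 18, with 21 as the highest other, so chance cannot be excluded for their number. The 10 splits of 6 libraries are too few for a share under 0.05, but they can show a larger share. At P56 the real split gave 3648 genes and the highest other 1 (1 of 10 reached the real count), and 15 lists against 21 (5 of 10). At P3 the real split gave 0 genes by edgeR (681 at an unadjusted p under 0.05, 1 gene by DESeq2) and the highest other 1 (10 of 10), and 12 lists against 13 (5 of 10). With 5 of 10 splits at the real count or above, chance cannot be excluded for the number of lists at P56 and at P3 either. For age in WT it gave 9793 genes against 0 (1 of 10).

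The first pattern is the set of 3648 genes at P56, with matrix genes among them. A difference in library size is argued against by thinning all libraries to the smallest total, after which 91.7% of the calls (3347) were still made with the same sign. A lower share of heart muscle cells, with the markers of all other cell types raised alike, is argued against. The median of the fibroblast markers lay 1.23 above that of the endothelial markers, with quartiles of 0.41 to 1.44 against -0.43 to -0.22. A lower share that goes along with more fibroblasts is not excluded by these values, also for the muscle and mitochondrial transcripts that fell. More fibroblasts remain a candidate explanation for the matrix genes: the 10 fibroblast markers outside the matrix list had a median of 0.75 (quartiles 0.31 to 1.13) beside matrix quartiles of 0.78 to 2.18, too close to decide. In these hearts, for which the labels name no sorting of cells, the abundant Col1a1 and Col3a1 stood at 453.5 and 506 CPM against 150.6 and 291.1 CPM in WT, and a response to the transgene, the difference the design names, stays open as well.

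The second pattern is the absence of calls at P3 together with Dyrk1b at the WT level. Changes as large as at P56 that were missed for lack of power are argued against: for the 803 genes called at P56 with at least a 2-fold change, the P3 change in the P56 direction had a median of -2.3% of the P56 log2 change (quartiles -12.6% to 7.9%), and 43.2% of these genes had the same sign at P3. An exchange of labels between the P3 groups as the cause of the pattern is argued against, since it would leave raised Dyrk1b in a library labelled WT, where the highest level was 78.1 CPM against 596 CPM in the lowest DYRK1B-Tg heart at P56. Whether each label at P3 is right cannot be read from Dyrk1b, as no library at P3 had a raised level. Too little power for single genes stays open for a minority of them: for 79.8% (641) of the 803 the 95% interval at P3 excluded the midpoint between no change and the P56 change, just under the bound of 80% set for it. That the hearts labelled DYRK1B-Tg at P3 carry no transgene cannot be told apart from a transgene that is not yet transcribed, because a Dyrk1b change of 0.17 would be seen in either case and the counts do not separate the cDNA from the animal's own gene.

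The third pattern is that the effect of genotype at P56 ran against the change with age. Since both comparisons share the WT hearts at P56, some opposition arises without any effect. The covariance of -0.23 lay below the simulated range of -0.067 to -0.049, by -0.17 from its mean. The simulated genes varied independently of each other, so this range is too narrow for genes that vary together in a heart. It therefore cannot decide whether the shared hearts are the whole cause. The 3 WT hearts cannot be split into parts of at least 2, so part or all of the excess over independent lists may still come from them. The observed correlation over genes, -0.223, was smaller in size than the simulated -0.545. Opposite signs were likewise fewer than simulated, at 53.8% of genes against 66.7% to 68.4%. A return to the neonatal state that includes the cell cycle genes is argued against by their list. Its median at P56 was 0.04 (quartiles -0.29 to 0.26, and -0.11 to 0.19 for the median with 1 heart left out) where the fall with age was -2.84. This list alone cannot speak for the other neonatal genes. A return of part of the neonatal genes stays open: matrix genes had a median of 1.25 at P56 where the fall with age was -2.10, and fetal-type isoforms went both ways at P56 (5 higher, 2 lower, quartiles -0.18 to 1.06).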

How the results depend on the processing

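The sex term and the thinning of counts were chosen after the data were seen. With the sex term edgeR called 1852 genes higher and 1512 lower at P56. It called 1057 and 779 for the interaction, and 4620 and 4778 for age in WT. No call named for P56 changed direction under any alternative run, and Dyrk1b stayed between 0.10 and 0.23 at P3 and between 2.90 and 3.20 at P56. With a replicate block the P56 genes lower numbered 1060, the interaction genes 693 higher and 368 lower, and the P3 lists lower 5. Deviations from the group mean correlated between same-numbered WT and DYRK1B-Tg libraries, as labelled, at -0.229 to -0.013 at P3 and -0.09 to -0.015 at P56. These values give no sign of pairing, but with 3 libraries per group they cannot exclude it. The block also costs degrees of freedom. DESeq2 gave 1 gene lower at P3 and 1 gene called at both ages, where edgeR had 0 and 681 genes at an unadjusted p under 0.05; the cause was not tested. A minimum absolute log2 fold change of 1 by construction kept fewer: 593 higher and 210 lower at P56, 507 and 162 for the interaction, 2056 and 2103 for age. An estimated correlation left 0 lists higher and 0 lower at P3, 2 and 0 at P56, and 1 and 0 for the interaction, while fry gave 0 and 0, 7 and 10, and 7 and 9. Camera at the preset correlation had 9 and 3 at P3, 6 and 9 at P56, and 8 and 10 for the interaction. At P56 fry did not call complex I (fry adjusted p = 0.0641), complex IV (0.0817) and STAT3-linked targets (0.0774), which camera called. Lists called by fry alone were fetal-type isoforms (0.0463), ion channels and connexins (0.0307), and D-type cyclins and inhibitors of cyclin-dependent kinases (0.0193). The amino acid and mitochondrial stress response (0.00554) and Schwann cell markers (0.00122) were also called by fry alone. With each replicate left out in turn, P56 genes ran from 1491 to 1776 higher and 1331 to 1579 lower, and 2723 to 3054 of the 3648 calls were kept. Interaction genes ran from 930 to 1195 higher and 589 (without the library labelled DYRK1B-Tg P3 replicate 1) to 915 lower; age genes from 4517 to 4681 higher and 4703 to 4828 lower. P3 lists ran from 4 (without WT P3 replicate 1) to 9 higher and from 2 to 5 lower (5 without the library labelled DYRK1B-Tg P3 replicate 2 or 3); fewer samples lower the power of the gene test, and otherwise the cause was not tested. Leaving out replicates was not run for the genes called at both ages, since edgeR called 0 genes at P3 in every such fit. RLE size factors moved the median of all genes at P56 from -0.003 to -0.017. For the genes named by rule or in the text, 4242 values over all alternatives kept their side of the threshold, 123 fell short of it and 5 passed it newly; for the lists at P56 these were 461, 17 and 25. P56 libraries hold fewer counts than P3 libraries (11174527 to 13231968 against 15742474 to 17095351), which limits the comparison of weakly transcribed genes across ages.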

Other observations

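The test of transcription in proportion to Myh6 was chosen only after the result was seen. At P56, genes that shape the heart's electrical activity went both ways in DYRK1B-Tg hearts. Of 22 ion channel and connexin genes 7 fell and 4 rose, 9 and 4 when adjusted over the list alone, with a median of -0.27 (edgeR and camera, adjusted p = 0.0695 for the list). The median was -0.18 without DYRK1B-Tg replicate 1, the list was called without DYRK1B-Tg replicate 3 (adjusted p = 0.0293), and 2 genes rose without WT replicate 2 or DYRK1B-Tg replicate 2. Kcnip2, a subunit of the transient outward potassium current, stood at -1.22 (SE 0.14, adjusted p = 7.7e-05) and Kcnj2, of the inward rectifier, at -1.08 (SE 0.14, adjusted p = 1.46e-04). The increases included Kcne1 (1.03, SE 0.23) and Hcn4 (0.66, SE 0.20). In glycolysis and glucose uptake 2 of 21 genes rose, Pfkp, the platelet-type phosphofructokinase (1.11, SE 0.12, adjusted p = 4.46e-05), and Ldha, the muscle-type lactate dehydrogenase (0.69, SE 0.09, adjusted p = 1.66e-04). In the same list 4 fell, among them Ldhb, the heart-type enzyme (-0.46, SE 0.07, adjusted p = 5.42e-04), and the list was not called (adjusted p = 0.507). Fetal-type isoforms (camera adjusted p = 0.361), adult-type muscle isoforms (0.0749, and 0.0331 without WT replicate 2) and calcium handling genes (0.777) were not called by camera either. With fry the fetal-type isoforms were called (adjusted p = 0.0463).

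Cell cycle genes stayed near the WT level at P56, with a median of 0.04 over 37 genes (adjusted p = 0.618). The calls were Cenpa (0.79, SE 0.14, adjusted p = 0.00166), a histone of the centromere, and Cenpf (-1.73, SE 0.18, adjusted p = 4.14e-05), a kinetochore protein. Ccnd2, cyclin D2, fell from 205 ± 18.5 to 74.0 ± 7.62 CPM (-1.47, SE 0.13, adjusted p = 1.36e-05). Cdkn1c, an inhibitor of cyclin-dependent kinases, stood at -1.02 (SE 0.18, adjusted p = 0.0013) and Cdkn2b, another, at 2.18 (SE 0.43, adjusted p = 0.00278); their list was not called (adjusted p = 0.271). Of 22 genes of the amino acid and mitochondrial stress response 8 rose and 3 fell, with a median of 0.43 (adjusted p = 0.0548). Leaving out WT replicate 2 (0.0336), DYRK1B-Tg replicate 2 (0.014) or replicate 3 (0.0207) called that list, while its median was 0.15 without DYRK1B-Tg replicate 1. Atf3, a stress-induced transcription factor, rose by 2.60 (SE 0.27, adjusted p = 3.83e-05) and Pycr1, of proline synthesis, by 1.49 (SE 0.23, adjusted p = 6.39e-04), while Shmt2, of mitochondrial serine use, fell (-0.54, SE 0.07, adjusted p = 2.13e-04). Hspa1a, a heat shock protein on the list of immediate early genes, rose by 3.57 (SE 0.47, adjusted p = 1.96e-04), but its counts are uncertain because of its near-identical copy Hspa1b. Antioxidant enzymes (adjusted p = 0.81), interferon-stimulated genes (0.701), cytokines and chemokines (0.821), T and NK cell markers (0.81), granulocyte markers (0.864), erythroid markers (0.81), skeletal muscle markers (0.365), Schwann cell markers (0.151) and thymocyte markers (0.324) were not called as lists at P56.

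DYRK1B-Tg replicate 1 at P56 differed from the other DYRK1B-Tg hearts of that age in several transcripts, chosen after their values were seen. It held less Dyrk1b (596 CPM against 928.6 and 870.6 CPM) and more Serpina3n, an acute phase protein (339 CPM against 20.9 and 28.04 CPM), Lcn2 (42.6 CPM against 22.3 and 7.66 CPM), Timp1 (33.5 CPM against 12.8 and 17.1 CPM) and Fos (17.7 CPM against 3.01 and 3.57 CPM). Without this heart 15 of 17 tested stress markers and 32 of 36 matrix genes were called higher.

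One hypothesis on the P3 hearts was that the transgene may be transcribed in proportion to Myh6, whose promoter it carries. Myh6 in the libraries labelled DYRK1B-Tg at P3 reached 52% of its level in DYRK1B-Tg at P56 (16212 against 31205 CPM), so that an excess of at least 259.3 CPM of Dyrk1b over WT would follow from the lowest of the P56 hearts. The highest excess of a library at P3 was 17.8 CPM. Hearts without the transgene would give the same, so the proportion stays open.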
